A study of Arabidopsis thaliana with 24 samples.

How the data were processed

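Developing seeds of Arabidopsis thaliana Col-0 were sampled at 12, 15, 18 and 20 days after pollination (DAP). Total RNA and polysomal RNA, the transcripts carried by several ribosomes at once, were each measured at every stage. The 8 groups of fraction and stage held 3 biological replicates each, which gave 24 biotin-labelled, one-colour arrays. Per the labels, a replicate pooled the seeds of several plants from a blocked planting. The deposited values are log2 levels of 1 probe set per locus, made by the authors with RMA, for which the submitters' processing notes give no version. RMA subtracts background, normalizes the arrays to one another and summarizes the probes of a set. The labels state neither the array design, nor which arrays were normalized together, nor a genome build, so no coordinates are given. Arrays give no count depth. Their number, 3 per group, limits the precision.

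Every one of the 27827 loci in the table was tested, without a filter on dim loci. Gene names and gene classes were looked up by locus in a RefSeq gene table of assembly TAIR10.1, where 27241 loci were found and 586 were not. That table was used for names, classes and the order of loci. Another 182 loci, in 88 sets, had values identical to those of another locus on all 24 arrays. They were kept in the tests and were not named one by one. A total of 37 of them were mitochondrial, and 33 of the sets joined a mitochondrial locus with a locus of chromosome 2.

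Changes were tested in R 4.3.3 with limma 3.58.1. One linear model held the 8 groups over all 24 arrays and left 16 residual degrees of freedom, and its moderated tests shared one estimate of the spread per locus. Comparisons were 20 against 12 DAP and each pair of consecutive stages within a fraction, polysomal against total RNA at each stage and over the mean of the 4 stages, and the change of the polysomal to total ratio between 12 and 20 DAP, which is the interaction of fraction and stage. Moderated F tests covered any change over the 4 stages. P values were adjusted over the loci after Benjamini and Hochberg, with a threshold of 0.05. A ratio of polysomal to total RNA on normalized arrays is relative to the other transcripts on the same arrays. It does not measure the share of all transcripts that sat in polysomes.

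A total of 21 gene lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Pathway lists covered seed storage proteins, oil body proteins, fatty acid and triacylglycerol synthesis, LEA (late embryogenesis abundant) proteins and dehydrins, heat shock proteins and factors, and raffinose family synthesis with a seed peroxiredoxin. They also covered photosynthesis, chlorophyll breakdown, cytosolic ribosomal proteins, translation factors, maturation transcription factors, abscisic acid with gibberellin and dormancy, reserve lipid mobilisation, the cell cycle, and expansins with xyloglucan endotransglucosylases. Marker lists covered seed coat flavonoids, seed coat mucilage, the endosperm and the silique valve, a fruit tissue that seed samples could hold. Organelle-encoded transcripts (92 mitochondrial and 15 plastid loci) and 706 non-coding RNA genes formed the last lists. The camera test was also run with a correlation estimated from the data. A list's count is given over all genes tested and, where said, adjusted over the list alone.

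Lists, comparisons, tests and the rule for naming genes were fixed before the data were examined. The rule named, for 5 comparisons, the 6 largest rises and the 6 largest falls with adjusted p under 0.05 whose replicate values did not overlap between groups (adjusted p alone for the change of the ratio). It also named the 2 largest called changes of each list, and 10 genes whatever their result (ABI3, FUS3, LEC1, ABI5, DOG1, HSFA9, CRA1, OLEO1, EM1 and EM6). Chance alone keeps the replicate values of 3 against 3 arrays apart in 10% of comparisons of unchanged loci. Genes named outside this rule are said to be so.

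The steps were tested on simulated data of 27827 genes, of which 100 were changed by 1 and 100 by 2 log2 units, with one replicate spread per gene for the 12 DAP arrays and another for the later arrays, both taken from the real data. For total RNA at 20 against 12 DAP, the model over all arrays recovered 26% of the smaller and 86% of the larger changes, and 161 of its 279 calls were false. For polysomal against total RNA at 12 DAP it recovered 40% and 88%, and 1353 of 1496 calls were false. For the same comparison at 20 DAP it recovered 15% and 87%, with 1 false call among 110. For the change of the ratio it recovered 12% and 55%, and 116 of 186 calls were false. One shared spread thus understated the error of the noisier 12 DAP arrays in the simulation, where few genes were changed. The false share at the larger proportions called in the real data was not simulated. Fitted to the compared groups alone, the simulated data gave 0 calls for total RNA at 20 against 12 DAP and for the fractions at 12 DAP, 105 calls with 5 false for the fractions at 20 DAP, and 9 calls with 2 false for the change of the ratio. The camera test found a further list of 40 genes, shifted by 1 log2 unit, in each of these comparisons and called none of 100 unshifted lists. The simulated noise was independent between genes, so this could not show false calls of lists whose genes vary together.

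Alternatives tried were centring each array on its median, repeated quantile normalization, cyclic loess, leaving out the 30% dimmest loci, a 2-fold threshold, array weights, a fit with trend and robust settings, a fit to the compared groups alone, the replicate number as a block, the other list tests of limma, and leaving out each array in turn. Fits without the 12 DAP arrays, comparisons with 15 DAP in place of 12 DAP, and the fit to the compared groups alone for lists and named genes were chosen after the data had been seen. Replicate numbers were not used as pairs.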

Results

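Levels of 27827 loci were measured in developing seeds of Arabidopsis thaliana, in total RNA and in polysomal RNA, at 12, 15, 18 and 20 days after pollination (DAP). Each of the 8 groups held 3 arrays. Between 12 and 20 DAP a seed goes from filling with oil and protein towards drying and rest. The comparisons ask how the transcripts of a seed change over that time, and whether those on polysomes follow. Changes are log2 differences ± SE from limma with n = 3 arrays per group, and p values are adjusted.

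The 6 arrays of 12 DAP stood apart from the 18 later arrays. Their levels spread less over genes, with an SD of 1.39 to 1.71 log2 units against 2.13 to 2.43. Their replicates correlated at 0.739 to 0.851 across genes, against 0.955 to 0.990 later, where genes are not independent replicates. The median SD between replicates was 0.532 in total and 0.567 in polysomal RNA at 12 DAP, against 0.175 to 0.301 later. The SEs printed below come from the fit to all 24 arrays, except where a fit without the 12 DAP arrays is named. The spread shared by all 24 arrays mostly understates that of the 12 DAP arrays and overstates that of the later ones. Beside the counts over all loci changed from 12 to 20 DAP, or different between the fractions at 12 DAP, stand those from the compared arrays alone, and genes named by the naming rule for these comparisons whose call ended there are said to be so. List and family counts have them only where said, and can be smaller there. For ribosomal proteins in total RNA 83 rose and 2 fell with the compared arrays alone, against 114 and 5. The median locus changed from 12 to 20 DAP by -0.311 in total and by -0.50 in polysomal RNA, and by 0.00693 and -0.0645 after repeated quantile normalization. Changes below are tested against 0 as deposited, with no shift subtracted, so small ones depend on the scaling.

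**Figure D1:**
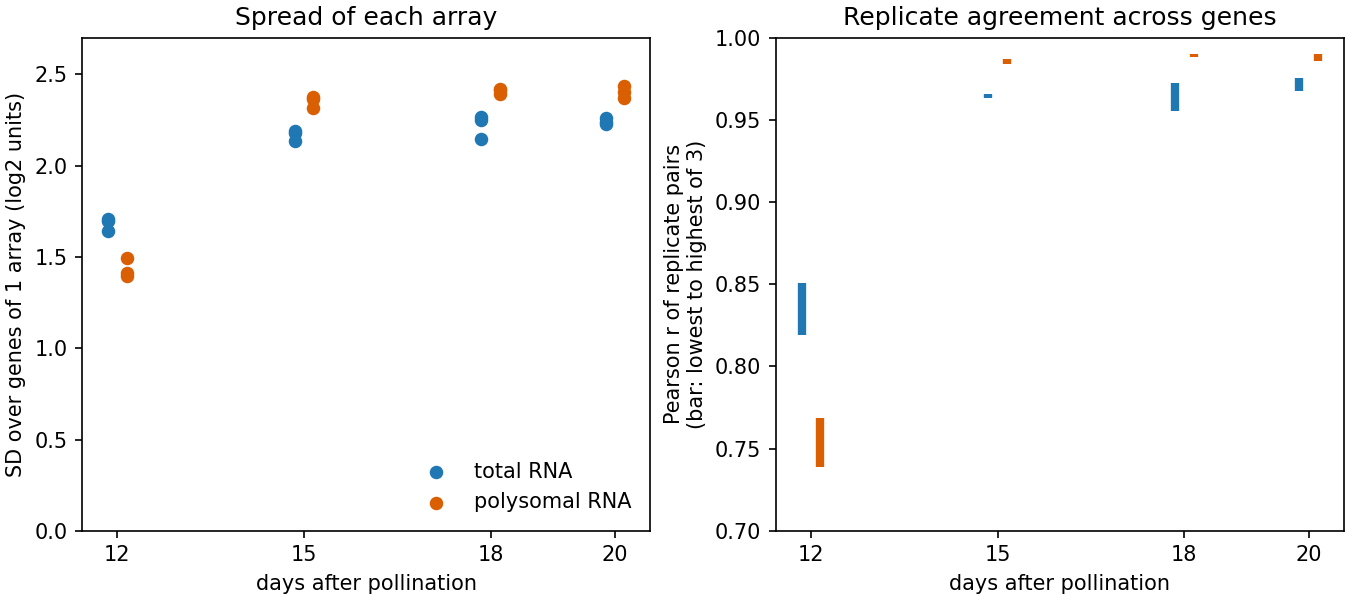
Left, SD over genes of the log2 levels of each array against days after pollination, for total and polysomal RNA; right, bars from the lowest to the highest Pearson correlation across genes between replicate arrays of a group. The 12 DAP arrays lie below all later arrays in both panels.

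Genes for light harvesting fell in total RNA between 12 and 20 DAP. LHCB1.3 and LHCB1.5, which encode chlorophyll-binding antenna proteins, changed by -8.01 ± 0.41 and -6.54 ± 0.31 (adjusted p = 1.6e-13 and 5e-14). Of 51 photosynthesis genes 50 fell and 0 rose (51 fell adjusted over the list alone), with a median of -4.05 (camera adjusted p = 5.1e-24). NYE2 and NYE1, which start the breakdown of chlorophyll, rose by 6.15 ± 0.28 and 3.38 ± 0.21. With them 5 of 8 chlorophyll breakdown genes rose and 0 fell, also over the list alone, with a median of 2.14 (adjusted p = 0.0012). In the same comparison all 5 markers of the silique valve fell (median -1.73), as did 17 of 18 flavonoid and 10 of 12 mucilage markers of the seed coat. With an estimated correlation the adjusted p was 0.00078 for photosynthesis and 0.017 for chlorophyll breakdown, and cyclic loess ended the latter call at a median of 0.815.

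Genes that make fatty acids fell while genes that break oil down rose. ACP1, an acyl carrier protein, and BCCP2, a subunit of the enzyme that starts fatty acid synthesis, changed by -6.21 ± 0.29 and -4.43 ± 0.27. Of 31 genes for fatty acid and triacylglycerol synthesis 24 fell and 3 rose, the same over the list alone, with a median of -2.06 (adjusted p = 2.1e-06; adjusted p = 0.0021 with an estimated correlation). The 3 that rose were DGAT1 (4.09), GPT1 (1.82) and PDAT1 (0.76), named outside the naming rule, and DGAT1 and PDAT1 add the last acyl chain to the oil molecule. ICL, which feeds the glyoxylate cycle, rose by 4.54 ± 0.21, and CSY3, a peroxisomal citrate synthase, by 4.03 ± 0.43. Of 16 genes for reserve lipid mobilisation 15 rose and 1 fell, also over the list alone, with a median of 3.28 (adjusted p = 1.6e-08; 0.0015 with an estimated correlation). With the compared arrays alone 23 of the first list fell and 15 of the second rose.

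Genes of desiccation tolerance rose in total RNA. M17 and AT4G36600, of the LEA (late embryogenesis abundant) proteins thought to protect dry cells, rose by 4.96 ± 0.32 and 4.65 ± 0.40. Of 35 LEA genes 27 rose and 7 fell, also over the list alone, with a median of 1.90 (adjusted p = 6.6e-08), for which the adjusted p = 0.054 with an estimated correlation and the median was 0.0216 under cyclic loess. HSP15.7, HSP90.1 and the seed heat shock factor HSFA9 rose by 5.02 ± 0.47, 4.36 ± 0.26 and 3.81 ± 0.32. Of 20 heat shock genes 17 rose and 2 fell, also over the list alone, with a median of 1.76 (adjusted p = 2.6e-06; 0.00078 with an estimated correlation), and cyclic loess ended that call at 0.405. GOLS1, which starts the synthesis of raffinose sugars, rose by 4.58 ± 0.27. SIP2, which breaks raffinose down, rose by 4.77 ± 0.24. Of the 6 genes of raffinose synthesis and seed peroxiredoxin 5 rose and 1 fell, also over the list alone, with a median of 2.66 (adjusted p = 0.0012; 0.028 with an estimated correlation).

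Storage and oil body transcripts stood higher at 15 DAP than at 12 or 20 DAP as deposited. The mean median level of storage proteins was 10.34, 11.86, 11.37 and 11.17 from 12 to 20 DAP, and that of oil body proteins 10.02, 11.62, 11.23 and 11.25. CRA1, which encodes a 12S globulin, did not change detectably (-0.13 ± 0.19, adjusted p = 0.59), and its sign turned under median centring and quantile normalization. AT2G18540 and PAP85, both vicilin-like, rose by 1.94 ± 0.24 and 1.81 ± 0.22, though both signs turned under cyclic loess. Of 13 storage protein genes 4 rose and 3 fell, also over the list alone, with a median of 0.279 that was not called (adjusted p = 0.39). CLO2 and OLEO5, which coat oil bodies, rose by 3.09 ± 0.25 and 1.23 ± 0.20, OLEO5 with the opposite sign under cyclic loess, and OLEO1 did not pass (0.40 ± 0.19, adjusted p = 0.077). Of 7 oil body genes 5 rose and 1 fell, also over the list alone, with a median of 1.2 (adjusted p = 0.019), which became -0.996 under cyclic loess. The adjusted p = 0.17 with an estimated correlation for this list. EM1 and EM6, LEA proteins of the late seed, rose by 1.11 ± 0.21 and 1.21 ± 0.20, again with turned signs under cyclic loess.

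Regulators of the embryo split in total RNA. ABI5, which acts downstream of abscisic acid, rose by 2.88 ± 0.23, and ABI3 by 1.96 ± 0.31 (adjusted p = 8.9e-06), the latter with the opposite sign under cyclic loess. LEC1 and FUS3, which act earlier in embryo formation, changed by -2.71 ± 0.31 and -1.55 ± 0.30. Of 13 maturation transcription factors 7 rose and 5 fell, also over the list alone, and the list was not called (median 0.867, mean 0.0852, adjusted p = 0.53; -0.123 on quantile values). The kinase SNRK2.3 and the phosphatase AHG1, which pass on and dampen the abscisic acid signal, rose by 5.90 ± 0.30 and 4.23 ± 0.28. DOG1, which sets the depth of dormancy, rose by 1.14 ± 0.31 (adjusted p = 0.0027), but by only 0.34 on quantile values (adjusted p = 0.42) and with the opposite sign under cyclic loess. Its mean level was 5.82, 8.77, 7.03 and 6.96 from 12 to 20 DAP. Of 26 genes of abscisic acid, gibberellin and dormancy 13 rose and 5 fell, also over the list alone, with a median of 0.565 (adjusted p = 0.019; 0.028 with an estimated correlation), lost on quantile values (0.299, adjusted p = 0.19) and -0.208 under cyclic loess.

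Transcripts of the seed coat and of growth fell in total RNA. TT10 and TT4, which make and oxidise the brown flavonoids of the coat, changed by -6.52 ± 0.30 and -6.06 ± 0.26, and of 18 flavonoid markers 17 fell and 0 rose, with a median of -2.35 (adjusted p = 1.2e-07; 0.0014 with an estimated correlation). BXL1 and GATL5, which act on cell wall sugars, changed by -5.70 ± 0.31 and -4.35 ± 0.32, and of 12 mucilage markers 10 fell and 0 rose, with a median of -2.56 (adjusted p = 3.7e-05; 0.0015). SYP111 and CDC20.1, used in cell division, changed by -3.74 ± 0.40 and -2.58 ± 0.38. Of 28 cell cycle genes 14 fell and 1 rose, with a median of -0.898 (adjusted p = 0.013; 0.028), lost on quantile values (-0.279, adjusted p = 0.084) and 0.0524 under cyclic loess. EXPA1 and EXPA10, which loosen cell walls, changed by -3.50 ± 0.36 and -3.03 ± 0.30, and of 16 genes of that list 11 fell and 0 rose, with a median of -1.34 (adjusted p = 0.0020; 0.014). All of these counts were the same over each list alone. SUC5, a sugar carrier, and ALE1, a protease, changed by -3.98 ± 0.45 and -2.15 ± 0.31, and of 12 endosperm markers 7 fell and 1 rose (8 fell over the list alone), with a median of -0.929 (adjusted p = 0.042), 3 falling with the compared arrays alone and 2 on quantile values, and the adjusted p = 0.055 with an estimated correlation. SHP2 and SHP1, of the fruit wall, changed by -4.28 ± 0.49 and -2.92 ± 0.32, and all 5 silique markers fell, also over the list alone, with a median of -1.73 (adjusted p = 0.013; adjusted p = 0.12 with an estimated correlation). The endosperm call ended without total 12 DAP replicate 2 (median -0.629), total 12 DAP replicate 3 (-0.731) or total 20 DAP replicate 1 (-0.620), on quantile values (-0.291) and under cyclic loess (-0.236), which also ended the silique call (-0.734).

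Transcripts for building ribosomes rose slightly as deposited, a direction that cyclic loess turned. AT2G32220 rose by 3.21 ± 0.33 and AT3G28500 changed by -3.55 ± 0.39. Of 193 cytosolic ribosomal protein genes 114 rose and 5 fell, also over the list alone, with a median of 0.816 (adjusted p = 1.2e-07), but the adjusted p = 0.071 with an estimated correlation, and the median was 0.0911 on quantile values (35 rose and 30 fell, adjusted p = 0.86) and -0.795 under cyclic loess. EIF2-GAMMA and EIF2-BETA, which bring the first amino acid to the ribosome, rose by 2.98 ± 0.38 and 2.96 ± 0.27. Of 35 translation factors 23 rose and 1 fell, also over the list alone, with a median of 1.43 (adjusted p = 9.8e-07; 0.017 with an estimated correlation), lost on quantile values (0.481, adjusted p = 0.059) and -0.429 under cyclic loess. ATMG01030 and ATCG00230, of the mitochondrial and plastid genomes, changed by -4.01 ± 0.35 and -3.96 ± 0.28. Of 107 organelle-encoded transcripts 93 fell and 0 rose (94 fell over the list alone), with a median of -2.11 (adjusted p = 3.5e-18; 0.0076). Among 706 non-coding RNA genes, AT2G47895 changed by -7.20 ± 0.45 and AT5G63195 by 5.23 ± 0.33, 115 rose and 244 fell (111 and 223 over the list alone), and the list was not called at the preset correlation (median -0.499, adjusted p = 0.059; 0.043 with an estimated correlation). On quantile values 117 of them rose and 116 fell, with a median of -0.0571.

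In total RNA 17441 loci changed between 12 and 20 DAP, 7936 of them upwards and 14627 by at least 2-fold. Largest rises, after NYE2, were those of UGE3 (6.09 ± 0.33), AT5G66430 (5.95 ± 0.23), RHA1B (5.94 ± 0.35), SNRK2.3 and RAP2.1 (5.85 ± 0.23), among genes whose replicates did not overlap. UGE3 interconverts nucleotide sugars and RAP2.1 is a stress transcription factor. Largest falls were those of AT1G62000 (-9.32 ± 0.35), AT1G62060 (-9.24 ± 0.39), AT1G62070 (-8.98 ± 0.34), AT1G62080 (-8.85 ± 0.26), AT4G15750 (-8.75 ± 0.37) and AT1G62220 (-8.16 ± 0.34). Leaving out the dimmest loci ended the calls of oil body proteins (median 1.2), hormone and dormancy genes (1.14), cell cycle genes (-0.704) and endosperm markers (-0.578). The count was 14270 with the compared arrays alone, 11676 on quantile values (6354 upwards), 15605 after median centring (9452 upwards) and 10558 under cyclic loess. On quantile values the falls numbered 6 for cell cycle genes and 2 for silique markers, and the rises 13 for translation factors.

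**Figure D2:**
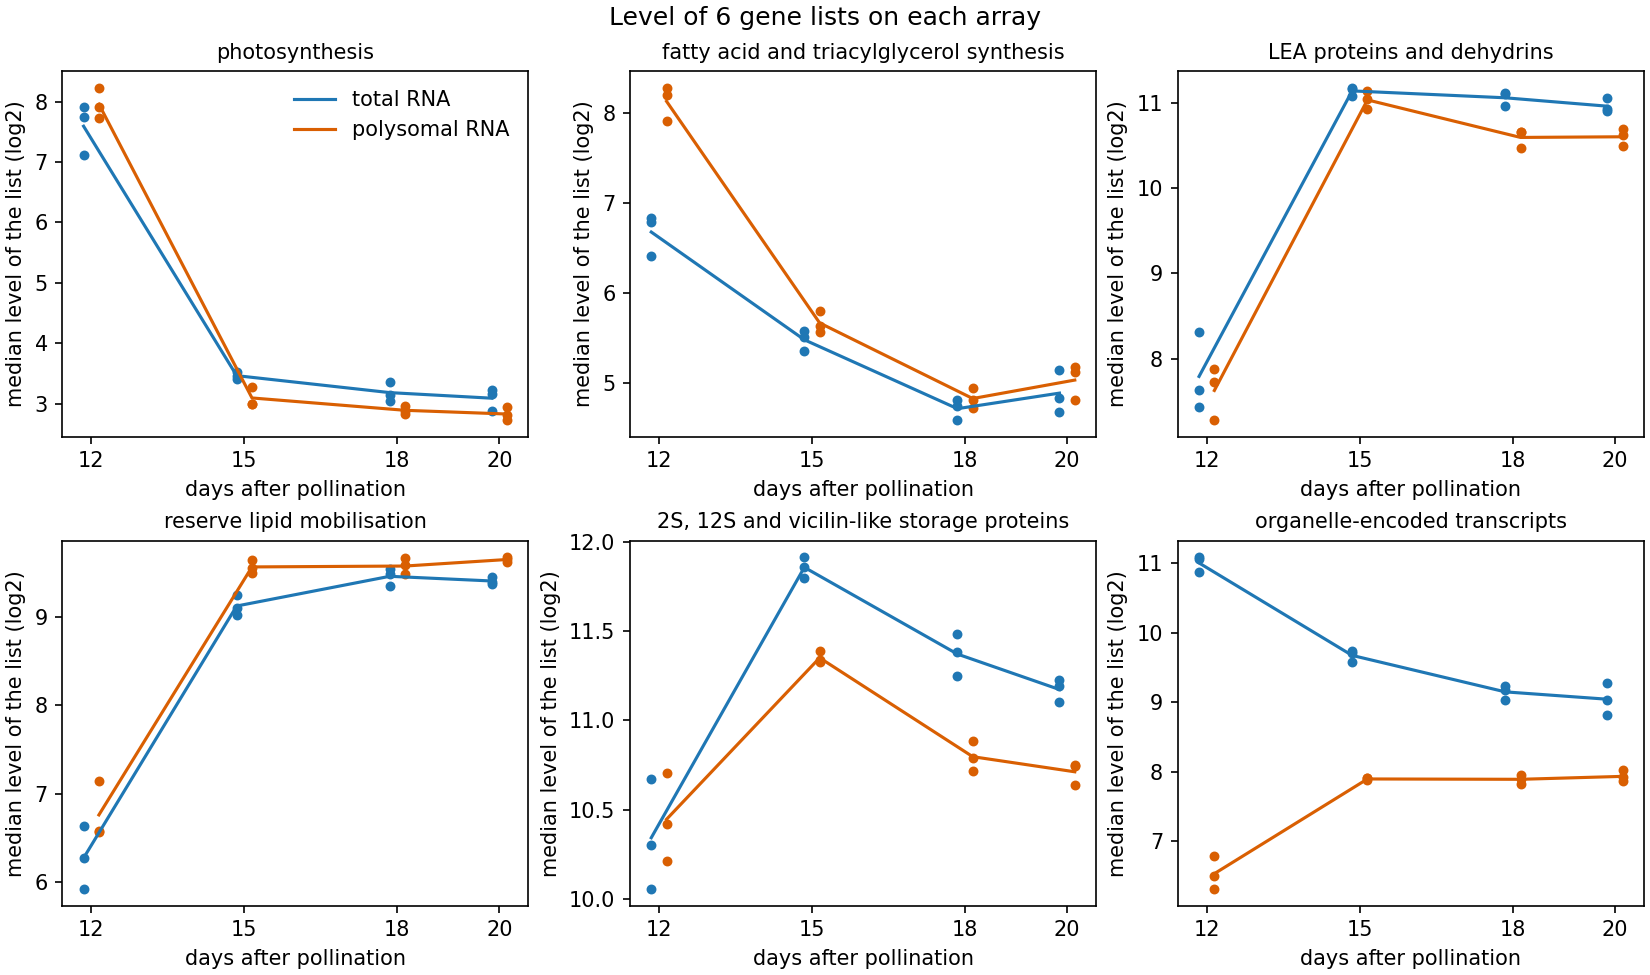
Median log2 level of 6 gene lists on each array against days after pollination, for total and polysomal RNA, with lines through the means of 3 arrays. Photosynthesis fell from a mean of 7.59 to 3.09 in total RNA, and organelle-encoded transcripts from 11.01 to 9.05 in total RNA but stood at 6.53 and 7.93 in polysomal RNA, where cyclic loess turned the sign of that rise.

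Most of the change lay between 12 and 15 DAP, a step that rests on the 12 DAP arrays, which stand apart. Counts of the later steps share one spread with those arrays, and a fit without them called 3720 loci from 15 to 18 DAP. Photosynthesis genes had a mean median level of 7.59 at 12 DAP and 3.47, 3.19 and 3.09 at 15, 18 and 20 DAP. LEA genes stood at 7.79, then 11.14, 11.06 and 10.96. Over the 4 stages 17005 loci changed in total RNA (10640 on quantile values). From 12 to 15 DAP 15273 changed, 6946 upwards (10181 on quantile values, and 8076 of 13384 upwards after median centring). From 15 to 18 DAP 722 changed, 356 upwards. That count was 433, 389 and 382 without total 15 DAP replicates 1, 2 and 3, 313 and 346 without total 18 DAP replicates 1 and 2, and 245 on quantile values (67 upwards), and under cyclic loess 245 of 674 were upwards. From 18 to 20 DAP limma called 0 loci, with 803 at an unadjusted p under 0.05, and 0 and 305 on quantile values.

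A fit without the 12 DAP arrays, chosen after the data had been seen, showed the later course more closely. SWEET10, a sugar transporter, changed by -4.36 ± 0.19 from 15 to 20 DAP in total RNA, and RNS1, a ribonuclease, by -4.42 ± 0.27. PS2, a phosphatase, and PDF1, of the outer cell layer, changed by -3.82 ± 0.21 and -3.70 ± 0.15. HB-2, a transcription factor, and KAT3, a potassium channel subunit, rose by 2.42 ± 0.24 and 2.3 ± 0.14. These 6 genes were picked after their values were seen. In that fit 5335 loci changed from 15 to 20 DAP, 3192 upwards, against 1407 in the fit to all arrays (764 upwards) and 416 there on quantile values (147 upwards). It gave 3720 changes from 15 to 18 DAP (2160 upwards) and 2 from 18 to 20 DAP, AT5G37360 (1.16 ± 0.16) and AT1G73450 (-1.70 ± 0.21), with 2275 at an unadjusted p under 0.05. Of 107 organelle-encoded transcripts 63 fell from 15 to 20 DAP, with a median of -0.765 (camera adjusted p = 3.6e-18; adjusted p = 0.13 with an estimated correlation). Storage proteins (6 of 13 fell, median -0.342, camera adjusted p = 1.4e-06) and the oil body, fatty acid, LEA and expansin lists were also called lower. Ribosomal proteins (46 of 193 rose and 2 fell, 0.269, adjusted p = 1.8e-06), translation factors and reserve lipid mobilisation were called higher. With an estimated correlation camera gave these further lists adjusted p = 0.12 to 0.35.

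Polysomal RNA showed the fall of the green seed too. LHCB1.3 and PSBO1, of the light reactions, changed by -8.50 ± 0.41 and -7.27 ± 0.28 between 12 and 20 DAP. Of 51 photosynthesis genes 49 fell and 0 rose, with a median of -3.98 (adjusted p = 2.2e-18; 0.0020 with an estimated correlation), and all 5 silique, 17 of 18 flavonoid and 10 of 12 mucilage markers fell with them. NYE2 and PPH, both for chlorophyll breakdown, rose by 4.56 ± 0.28 and 4.29 ± 0.36. Of 8 genes in that list 5 rose and 0 fell, with a median of 2.09 (adjusted p = 0.0029; 0.024), lost on quantile values (1.23, adjusted p = 0.17). ACP1 and BCCP2 changed by -7.09 ± 0.29 and -5.87 ± 0.27, and of 31 genes for fatty acid and triacylglycerol synthesis 26 fell and 4 rose, with a median of -3.12 (adjusted p = 2.3e-07; 0.0020). MLS, of the glyoxylate cycle, and PXA1, which carries fatty acids into the peroxisome, rose by 3.98 ± 0.22 and 3.58 ± 0.33, and of 16 genes for reserve lipid mobilisation 15 rose and 1 fell, with a median of 2.80 (adjusted p = 1.0e-06; 0.0043). All of these counts were the same over each list alone.

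Protective proteins rose on polysomes as well. HSP23.6 and HSP17.6A, small heat shock proteins, rose by 5.66 ± 0.29 and 5.01 ± 0.49, and HSFA9 by 4.70 ± 0.32. Of 20 heat shock genes 18 rose and 0 fell, with a median of 3.10 (adjusted p = 2.3e-07; 0.00032 with an estimated correlation). AT2G18340 and AT3G53040, of the LEA list, rose by 5.26 ± 0.28 and 5.17 ± 0.33, and of 35 LEA genes 25 rose and 5 fell, with a median of 1.91 (adjusted p = 1.8e-05; adjusted p = 0.13 with an estimated correlation). SIP2 and GOLS1 rose by 4.85 ± 0.24 and 4.42 ± 0.27, and of 6 genes of the raffinose list 4 rose and 1 fell, with a median of 3.0 (adjusted p = 0.0071; adjusted p = 0.066 with an estimated correlation). Storage proteins were not called, with 5 of 13 higher and 5 lower, a median of -0.251 (0.0948 on quantile values), a mean of 0.314 and adjusted p = 0.72, though AT2G18540 (3.44 ± 0.24) and SESA4 (2.39 ± 0.28) rose. Oil body proteins were not called either, with 2 of 7 higher and 3 lower and a median of 0.0503 (adjusted p = 0.92; -0.194 on quantile values), though CLO2 rose by 2.25 ± 0.25 and OLEO3 changed by -1.58 ± 0.22. All of these counts were the same over each list alone. EM1 rose by 1.12 ± 0.21, with the opposite sign under cyclic loess. With the compared arrays alone OLEO1 (-0.60 ± 0.19, adjusted p = 0.072), EM6 (0.50 ± 0.20, adjusted p = 0.13) and CRA1 (-0.43 ± 0.19, adjusted p = 0.18) did not pass.

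Among regulators on polysomes ABI5 rose by 4.32 ± 0.23, while L1L, LEC1 and FUS3 changed by -4.24 ± 0.32, -3.03 ± 0.31 and -1.46 ± 0.30. ABI3 rose by 1.44 ± 0.31 as deposited but by 0.00 on quantile values (adjusted p = 0.99), and DOG1 changed by 0.68 ± 0.31 as deposited (adjusted p = 0.14 with the compared arrays alone) but by -0.88 on quantile values. Of 13 maturation transcription factors 6 rose and 5 fell, and the list was not called (median 0.399, adjusted p = 0.55; -0.533 on quantile values). AHG1 and SNRK2.3 rose by 5.38 ± 0.28 and 5.14 ± 0.30, and of 26 genes of abscisic acid, gibberellin and dormancy 18 rose and 6 fell, with a median of 1.68 (adjusted p = 0.0024; 0.0087 with an estimated correlation), lost on quantile values (0.663, adjusted p = 0.051). Ribosomal protein genes SAG24 and PGY2 rose by 4.25 ± 0.47 and 4.05 ± 0.29, and of 193 in that list 106 rose and 19 fell (104 and 17 over the list alone). Their median was 0.813 as deposited (adjusted p = 5.7e-05; adjusted p = 0.16 with an estimated correlation) but -0.357 on quantile values, where 27 rose and 72 fell, and -1.04 under cyclic loess. EIF2-BETA and AT1G07930 rose by 3.34 ± 0.27 and 2.91 ± 0.34, and of 35 translation factors 25 rose and 1 fell, with a median of 1.35 (adjusted p = 2.5e-05; 0.029), which was -0.0254 on quantile values and -0.739 under cyclic loess. Counts over the list alone were the same for the regulators, the hormone genes and the translation factors.

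Seed coat and growth genes fell on polysomes. TT4 and TT10 changed by -5.77 ± 0.26 and -5.17 ± 0.30, and of 18 flavonoid markers 17 fell and 0 rose, with a median of -2.25 (adjusted p = 1.1e-05; 0.0043 with an estimated correlation). BXL1 and GATL5 changed by -5.79 ± 0.31 and -3.83 ± 0.32, and of 12 mucilage markers 10 fell and 1 rose, with a median of -1.99 (adjusted p = 0.0045; 0.014). SYP111 and CDC20.1 changed by -3.54 ± 0.40 and -3.0 ± 0.38, and of 28 cell cycle genes 23 fell and 2 rose, with a median of -1.32 (adjusted p = 0.0017; 0.011). EXPA1 and EXPA10 changed by -3.54 ± 0.36 and -3.25 ± 0.30, and of 16 genes of expansins and xyloglucan enzymes 14 fell and 1 rose, with a median of -1.63 (adjusted p = 0.0017; 0.011). SUC5 and ALE1 changed by -3.61 ± 0.45 and -2.51 ± 0.31, and of 12 endosperm markers 11 fell and 0 rose, with a median of -1.63 (adjusted p = 0.0063; 0.016), lost on quantile values (-0.816, adjusted p = 0.051). SHP2 and ALC changed by -3.14 ± 0.49 and -2.78 ± 0.39, and all 5 silique markers fell, with a median of -2.64 (adjusted p = 0.014; adjusted p = 0.14 with an estimated correlation). All of these counts were the same over each list alone.

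Organelle-encoded transcripts rose on polysomes as deposited, with the opposite sign under cyclic loess, while they fell in total RNA. ATMG00920 and ATMG01270, both mitochondrial, rose by 4.13 ± 0.33 and 3.45 ± 0.30, and of 107 such transcripts 60 rose and 13 fell, also over the list alone. Their median of 0.919 was called at the preset correlation (adjusted p = 1.6e-04; adjusted p = 0.16 with an estimated correlation), was 0.00411 on quantile values (31 rose and 28 fell) and turned to -1.21 under cyclic loess. By genome, 58 of 92 mitochondrial loci rose (median 1.04; 0.203 on quantile values), while 8 of 15 plastid loci fell (median -0.904). Of 706 non-coding RNA genes 140 rose, AT1G46554 by 5.16 ± 0.32 and AT1G11175 by 5.06 ± 0.32, and 355 fell (138 and 349 over the list alone), with a median of -0.814 (adjusted p = 0.014; 0.014), lost on quantile values (-0.22, with 123 up and 151 down) and 0.017 under cyclic loess.

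In polysomal RNA 21739 loci changed between 12 and 20 DAP, 9419 upwards and 19265 by at least 2-fold. Largest rises were those of AT1G47980 (6.63 ± 0.47), AT1G19490 (6.23 ± 0.21), AT5G50360 (6.08 ± 0.29), AT1G52560 (6.05 ± 0.34), TPS11 (5.98 ± 0.27) and AT2G38820 (5.97 ± 0.26), among genes whose replicates did not overlap. TPS11 belongs to the trehalose phosphate enzymes. Largest falls, beside LHCB1.3, were those of AT1G62220 (-9.13 ± 0.34), AT1G62060 (-8.95 ± 0.39), AT1G62000 (-8.67 ± 0.35), AT1G62080 (-8.50 ± 0.26) and AT5G38160 (-8.17 ± 0.34). Cyclic loess ended the polysomal calls of LEA proteins (median 0.158), chlorophyll breakdown (0.506), hormone and dormancy genes (0.0111), cell cycle genes (-0.306) and endosperm markers (-0.489). Leaving out the dimmest loci ended those of the raffinose list (3.0), ribosomal proteins (0.85), hormone and dormancy genes (1.76) and organelle-encoded transcripts (0.919). The count was 20127 with the compared arrays alone, 12041 on quantile values (6382 upwards), 19622 after median centring (11102 upwards) and 9568 under cyclic loess. On quantile values 8 translation factors rose and 8 fell, 11 hormone and dormancy genes rose and 3 fell, and the falls numbered 11 for cell cycle genes, 6 for expansins and xyloglucan enzymes and 5 for endosperm markers.

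Genes for making seed oil were among those that fell on polysomes after 15 DAP. FAE1, which lengthens fatty acids for seed oil, changed by -4.60 ± 0.25 from 15 to 20 DAP without the 12 DAP arrays, and LAC5 and ATSDI1 by -3.95 ± 0.32 and -3.77 ± 0.16, while PYK10, a glucosidase, rose by 2.22 ± 0.32. These 4, and 2 more below, were picked after their values were seen. Of 31 genes for fatty acid and triacylglycerol synthesis 12 fell and 3 rose over that time, with a median of -0.351 (adjusted p = 7.2e-05; 0.0080 with an estimated correlation). Storage proteins (6 of 13 fell, median -0.306, adjusted p = 2.5e-05) and LEA proteins (9 of 35 fell and 1 rose, -0.238, adjusted p = 5.7e-05) had lower p values at the preset correlation, and adjusted p = 0.095 and 0.17 with an estimated one. The oil body, heat shock, maturation factor and flavonoid lists were also called lower at the preset correlation. Ribosomal proteins and reserve lipid mobilisation were called higher. With an estimated correlation camera gave these lists adjusted p = 0.17 to 0.40. AT5G55620 (-5.14 ± 0.31) and AT1G62080 (-4.88 ± 0.25) fell more than FAE1. Over the 4 stages 21808 loci changed (11171 on quantile values), from 12 to 15 DAP 21192 changed (9054 upwards, against 6241 of 11743 on quantile values and 10896 of 18212 after median centring), and from 15 to 18 DAP 742 changed (320 upwards). The last count was 420, 368 and 374 without polysomal 15 DAP replicates 1, 2 and 3, 350, 332 and 368 without polysomal 18 DAP replicates 1, 2 and 3, 190 on quantile values (32 upwards), 726 under cyclic loess (226 upwards) and 3242 without the 12 DAP arrays (1828 upwards). From 18 to 20 DAP limma called 0 loci, with 100 at an unadjusted p under 0.05, 59 on quantile values and 549 without the 12 DAP arrays, 4 being called with array weights. From 15 to 20 DAP 938 loci changed (461 upwards), 238 on quantile values (60 upwards) and 3503 without the 12 DAP arrays (1999 upwards).

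Changes in total and polysomal RNA from 12 to 20 DAP went together across genes, which are not independent replicates, with a Pearson r of 0.835 and a Spearman rho of 0.80. LHCB1.3, TT4 and ACP1 fell in both, and SNRK2.3, AHG1 and GOLS1 rose in both. A total of 7224 loci rose in both, 7733 fell in both and 310 were called in opposite directions. Of these 252 fell in total and rose in polysomal RNA, 48 of which were organelle-encoded, and 58 went the other way. Calls in total RNA alone numbered 2174 and in polysomal RNA alone 6472, and such a gap is not a tested difference. Independent calls of these numbers would share 13630 loci in any direction. On quantile values r was 0.69, with 4088 loci up in both, 2548 down in both and 374 in opposite directions (5052 expected to be shared), and from 15 to 20 DAP without the 12 DAP arrays it was 0.606.

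Mitochondrial transcripts were scarce on polysomes at 12 DAP relative to other transcripts. ATMG00450, ATMG00880, ATMG00860, ATMG00820 and ATMG01250 were lower in polysomal than in total RNA by -8.34 ± 0.41, -8.10 ± 0.43, -7.96 ± 0.32, -7.74 ± 0.27 and -7.30 ± 0.27. AT2G07683, in the stretch of chromosome 2 treated below as a mitochondrial insertion, was lower by -7.39 ± 0.25. Mitochondrial ribosomes, which read mitochondrial transcripts, are not part of cytosolic polysomes. Of 107 organelle-encoded transcripts 99 were lower and 0 higher, also over the list alone, with a median of -4.22 (camera adjusted p = 2.0e-83; 1.6e-05 with an estimated correlation), and 87 were lower with the compared arrays alone. Mitochondrial loci had a median of -4.45 (91 of 92 lower), plastid loci of -0.838 (8 of 15 lower; -0.0439 on quantile values) and nuclear protein-coding genes of 0.11. Non-coding AT2G07746 and AT2G07745, of the same stretch of chromosome 2, were lower by -6.92 ± 0.57 and -4.94 ± 0.31.

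Genes for making fatty acids were enriched on polysomes at 12 DAP. AT1G24360 and LTA2 were higher by 2.80 ± 0.35 and 2.03 ± 0.29 (adjusted p = 0.0013 and 0.021 with the compared arrays alone). Of 31 genes of that list 20 were higher and 2 lower (21 and 2 over the list alone), with a median of 0.928 (adjusted p = 5.0e-06; 0.0038 with an estimated correlation), and 5 were higher with the compared arrays alone. HSP17.6A and HSP23.6 were lower by -4.34 ± 0.49 and -3.99 ± 0.29 (adjusted p = 0.0011 and 1.2e-04), and of 20 heat shock genes 10 were lower and 2 higher (12 and 2 over the list alone), with a median of -0.883 (adjusted p = 5.4e-04; 0.0038), and 5 lower with the compared arrays alone. OLEO5 and OLEO3 were higher by 1.03 ± 0.20 and 1.0 ± 0.22, and 6 of 7 oil body genes were higher, also over the list alone, with a median of 0.827 (adjusted p = 0.0063; adjusted p = 0.27 with an estimated correlation). With the compared arrays alone 0 of these 7 passed in limma and the list was not called (adjusted p = 0.095). The remaining 17 lists were not called at 12 DAP, with adjusted p from 0.11 for reserve lipid mobilisation to 1 for LEA proteins as deposited. On quantile values ribosomal proteins (75 higher, 15 lower, median 0.511, adjusted p = 0.0021), translation factors (0.636, adjusted p = 0.0059), reserve lipid mobilisation (1.06, adjusted p = 0.0032) and photosynthesis (0.735, adjusted p = 0.042) were called as higher. As deposited, median and mean differed in sign for storage proteins (0.0265 and -0.264), LEA proteins (0.219 and -0.0994), maturation transcription factors (0.0746 and -0.147) and silique markers (0.201 and -0.0363).

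Single genes differed within lists that were not called at 12 DAP, and only a part of them is named here. With all arrays 53 ribosomal protein genes were higher and 22 lower, as were 13 and 6 photosynthesis genes. With the compared arrays alone 1 was higher and 2 were lower in each of these lists. SESA4 and SESA2, which encode 2S albumins, were lower on polysomes by -2.39 ± 0.28 and -2.21 ± 0.25 (adjusted p = 0.010 and 0.012 with the compared arrays alone). LDOX and DFR, of flavonoid synthesis, were lower by -2.40 ± 0.33 and -2.14 ± 0.32 (adjusted p = 0.0043 and 0.014), and AT3G53040, of the LEA list, by -3.58 ± 0.33 (adjusted p = 7.1e-04). ABI5 (-1.64 ± 0.23, adjusted p = 0.054), HSFA9 (-1.15 ± 0.32, adjusted p = 0.24), DOG1 (0.92 ± 0.31, adjusted p = 0.34) and OLEO1 (0.68 ± 0.19, adjusted p = 0.42) passed with all arrays but not with the compared arrays alone. ABI3, FUS3, LEC1, CRA1, EM1 and EM6 were not called, with adjusted p from 0.16 to 0.99. ACAT2, of isoprenoid precursor synthesis, was the largest rise at 3.28 ± 0.33, followed by AT3G16895 (3.24 ± 0.45), OFP9 (3.06 ± 0.55), HSP15.7 (2.86 ± 0.47), AT1G56940 (2.83 ± 0.85) and GASA2 (2.80 ± 0.24).

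At 12 DAP 8750 loci differed between the fractions, 4463 higher on polysomes. Fitted to the 6 arrays compared, which keeps their own spread, limma called 1573, of which 252 were higher. The count was 1590 with array weights and 10012 on quantile values. HSP23.6, HSP17.6A, AT3G53040 and the mitochondrial genes named above were called both with the compared arrays alone and on quantile values.

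At 15 DAP mitochondrial transcripts were still lower on polysomes, with a median of -1.57 and 57 of 92 lower, and plastid ones had a median of -0.864 with 7 of 15 lower. Of the 107 organelle-encoded transcripts 64 were lower and 0 higher (73 lower over the list alone), with a median of -1.32 (adjusted p = 1.2e-53; 2.5e-04 with an estimated correlation). Translation factors were higher with a median of 0.408 (adjusted p = 0.0021), with 1 of 35 past the threshold (0 over the list alone), and fatty acid synthesis with 0.39 (adjusted p = 0.037; 1 of 31, also over the list alone). Expansins and xyloglucan enzymes were lower with -0.589 (adjusted p = 0.027; 3 of 16, 6 over the list alone), and storage proteins with -0.272 (adjusted p = 0.037; 0 of 13). The adjusted p = 0.19, 0.19, 0.11 and 0.30 with an estimated correlation for these 4 lists, none of which was called on quantile values (medians 0.227, 0.176, -0.298 and -0.164). Reserve lipid mobilisation was called higher there (0.387, camera adjusted p = 0.038), as at 18 (0.294, 0.044) and 20 DAP (0.283, 0.022). Without the 12 DAP arrays it and ribosomal proteins were called higher at 15 DAP (adjusted p = 0.0077 and 0.023; 0.30 and 0.49 with an estimated correlation). Without the 12 DAP arrays 14 translation factors (24 over the list alone) and 11 fatty acid genes were higher, 1 of the latter was lower, and 6 genes each of the expansin and storage lists were lower (adjusted p = 0.22, 0.11, 0.11 and 0.19 with an estimated correlation). With the compared arrays alone these counts were 6, 3, 4 and 0. Median centring turned the storage median to 0.00479 and ended its call, which also ended without total 15 DAP replicate 1 (-0.31) or polysomal 15 DAP replicate 3 (-0.237). The fatty acid call ended without polysomal 15 DAP replicate 2 (0.394). AT1G24360 was higher by 1.51 (adjusted p = 0.0066).

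Between the fractions 3295 loci differed at 15 DAP, 1218 higher on polysomes, and the all-gene median ratio stood at 0.351 after median centring, which raised the count to 5344, of which 3828 were higher. It was 762 on quantile values (171 higher), 6196 with the compared arrays alone (3014 higher) and 8643 without the 12 DAP arrays (4851 higher), so the balance of directions depends on the fit and the scaling. Leaving out 1 array gave 1986 and 2150 (total 15 DAP replicates 2 and 3) and 1939, 1827 and 1756 (polysomal 15 DAP replicates 1, 2 and 3).

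At 18 DAP mitochondrial transcripts had a median of -0.918 (46 of 92 lower) and plastid ones of -0.583 (6 of 15 lower). Of the 107 together 52 were lower and 0 higher (58 lower over the list alone), with a median of -0.852 (adjusted p = 2.7e-36; 0.0021 with an estimated correlation, and adjusted p = 0.060 with that correlation without the 12 DAP arrays). Translation factors were higher (median 0.269, 0 of 35 past the threshold), and LEA proteins (-0.356, 0 of 35), storage proteins (-0.336, 0 of 13, 3 over the list alone) and endosperm markers (-0.355, 3 of 12, 4 over the list alone) were lower, each with an adjusted p = 0.021. The adjusted p = 0.42, 0.51, 0.42 and 0.077 with an estimated correlation for these 4. On quantile values these 4 were not called (0.073, -0.136, -0.12 and -0.104), and median centring ended the LEA (-0.175) and storage (-0.155) calls. Without the 12 DAP arrays 7 translation factors were higher and 1 lower, and 15 LEA, 6 storage and 4 endosperm genes were lower (adjusted p = 0.39, 0.23, 0.23 and 0.060 for the lists with an estimated correlation). Without total 18 DAP replicate 1 the storage (-0.296), LEA (-0.311) and endosperm (-0.348) calls ended, and without total 18 DAP replicate 3 the translation call did (0.163). In all 2251 loci differed, 753 higher on polysomes, against 344 on quantile values (49 higher), 2850 after median centring (1645 higher), 4328 with the compared arrays alone (2023 higher) and 6887 without the 12 DAP arrays (3747 higher). Leaving out 1 array gave 604 (total 18 DAP replicate 3) and 915, 1002 and 925 (polysomal 18 DAP replicates 1, 2 and 3).

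At 20 DAP ATMG00820 and the plastid gene ATCG00250 were lower on polysomes by -4.04 ± 0.27 and -3.92 ± 0.32. Mitochondrial transcripts had a median of -0.718 (44 of 92 lower) and plastid ones of -0.484 (5 of 15 lower). Of the 107 together 49 were lower and 0 higher (52 and 2 over the list alone), with a median of -0.641 (adjusted p = 1.1e-32; 0.0037 with an estimated correlation, and adjusted p = 0.098 with that correlation without the 12 DAP arrays). Translation factors were higher with a median of 0.257 (adjusted p = 0.035; adjusted p = 0.45 with an estimated correlation), with EIF4G alone past the threshold (0.77 ± 0.21), also over the list alone. Without the 12 DAP arrays 5 were higher and 1 lower, and 4 and 1 with the compared arrays alone. Without the 12 DAP arrays LEA proteins (8 of 35 lower and 1 higher, median -0.252, camera adjusted p = 8.9e-04), storage proteins (5 of 13 lower, -0.208, adjusted p = 0.0084) and reserve lipid mobilisation (4 of 16 higher, 0.17, adjusted p = 0.041) were called too, with adjusted p = 0.33, 0.33 and 0.47 with an estimated correlation. With all arrays the call of translation factors ended without total 20 DAP replicate 1 (0.227), without polysomal 20 DAP replicate 1 (0.22) and on quantile values. FAE1, L1L and EXPA6 were lower by -1.22 ± 0.29, -1.50 ± 0.32 and -1.64 ± 0.31, and LTA2 was higher by 1.09 ± 0.29, none of which passed on quantile values (adjusted p from 0.12 to 0.47). The 10 genes named in advance were not called, from EM6 (-0.50 ± 0.20, adjusted p = 0.17) to DOG1 (0.46 ± 0.31, adjusted p = 0.48).

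The largest falls at 20 DAP were those of AT1G34910 (-5.54 ± 0.67), AT1G55990 (-4.93 ± 0.37), AT4G08370 (-4.85 ± 0.84), AT1G26240 (-4.70 ± 0.71), AT2G11778 (-4.59 ± 0.78) and AT3G06019 (-4.39 ± 0.60), also called on quantile values. The largest rises were those of AT5G28390 (2.73 ± 0.71), AT1G24240 (2.22 ± 0.51), AT5G17900 (2.18 ± 0.54), AT5G28900 (1.86 ± 0.49), AT4G09587 (1.85 ± 0.35) and AT3G09160 (1.76 ± 0.44), which were not called there. In all 999 loci differed, 239 higher on polysomes, against 189 on quantile values (13 higher), 1038 after median centring (419 higher), 3416 with the compared arrays alone (1578 higher) and 4139 without the 12 DAP arrays (2156 higher). Leaving out 1 array gave 534 and 427 (total 20 DAP replicates 2 and 3) and 417, 455 and 399 (polysomal 20 DAP replicates 1, 2 and 3). Over the mean of the 4 stages 10812 loci differed, 5751 higher (9358 of 13275 after median centring), of which 189 were higher and 1936 lower by at least 2-fold.

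**Figure D3:**
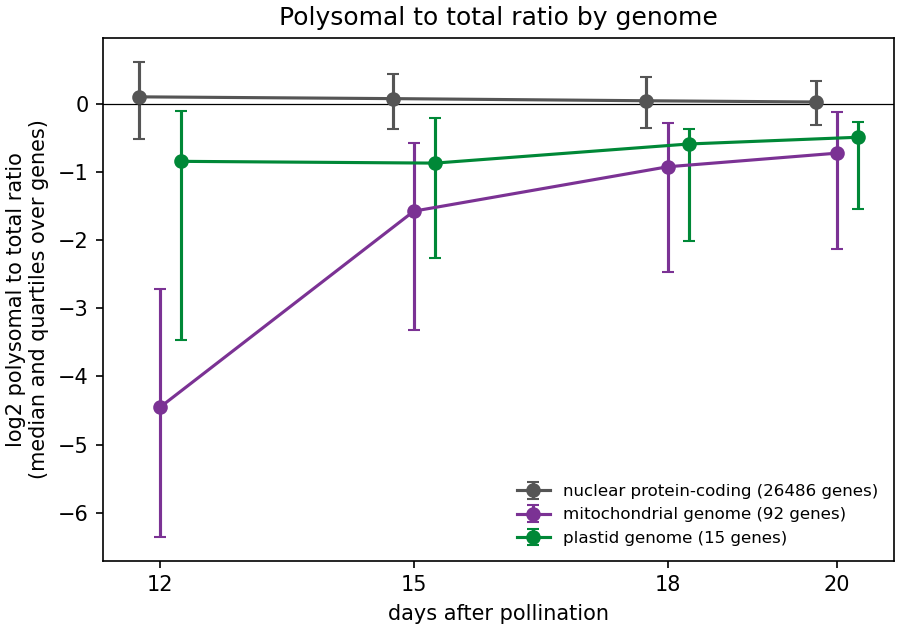
Log2 ratio of polysomal to total RNA against days after pollination for 26486 nuclear protein-coding, 92 mitochondrial and 15 plastid genes, as medians with bars from the lower to the upper quartile over genes. The mitochondrial median moves from -4.45 to -0.718 while the nuclear median stays between 0.0342 and 0.11.

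The gap between the fractions narrowed for mitochondrial transcripts from 12 to 20 DAP. ATMG01240, ATMG00450 and ATMG01030 gained 6.69 ± 0.65, 6.23 ± 0.58 and 6.08 ± 0.49 in the log2 ratio, and the nuclear loci AT5G27889, AT2G07798 and AT4G18690 gained 6.40 ± 0.46, 6.04 ± 0.34 and 5.79 ± 0.37. AT2G07798 lies in the stretch of chromosome 2 treated below as a mitochondrial insertion. Of 107 organelle-encoded transcripts 89 gained and 1 lost (96 and 2 over the list alone), with a median of 3.04 (camera adjusted p = 1.2e-68; 5.5e-05 with an estimated correlation), and 76 gained with the compared arrays alone. The 92 mitochondrial loci had a median of 3.58 (2.38 on quantile values) and the 15 plastid loci of 0.589 (-0.101 on quantile values). Non-coding AT2G07745 and AT2G07746, also of that stretch of chromosome 2, gained 4.59 ± 0.44 and 4.46 ± 0.80.

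Heat shock genes gained on polysomes and genes for oil lost between 12 DAP, whose arrays stand apart, and 20 DAP. HSP23.6 and HSP17.6A gained 4.12 ± 0.41 and 3.51 ± 0.70, and of 20 heat shock genes 7 gained and 2 lost (8 and 2 over the list alone), with a median of 0.625 (adjusted p = 6.1e-04; 0.0060 with an estimated correlation). AT1G22170, in the supply of carbon to fatty acids, and AT5G10160, of fatty acid synthesis, changed by -2.68 ± 0.63 and -2.27 ± 0.38 (adjusted p = 0.053 and 0.011 with the compared arrays alone). Of 31 genes of that list 8 lost and 1 gained (12 and 1 over the list alone), with a median of -0.885 (adjusted p = 4.2e-05; 0.0075), and 2 lost and 0 gained with the compared arrays alone. OLEO4 and OLEO2 changed by -1.18 ± 0.28 and -1.15 ± 0.29, and 5 of 7 oil body genes lost (6 over the list alone), with a median of -0.983 (adjusted p = 6.7e-04; adjusted p = 0.17 with an estimated correlation), while limma called 0 of the 7 with the compared arrays alone (adjusted p = 0.10 for OLEO4 and 0.12 for OLEO2). From 15 to 20 DAP, without the 12 DAP arrays, none of these 3 lists was called (medians -0.148, -0.185 and -0.0836, adjusted p = 0.19, 0.11 and 0.58). Of the remaining 17 lists none was called from 12 to 20 DAP as deposited. On quantile values 37 ribosomal protein genes lost and 4 gained (median -0.55, adjusted p = 8.2e-05), and photosynthesis (-0.669), translation factors (-0.313) and reserve lipid mobilisation (-0.582) were also called, each with adjusted p = 0.040. As deposited, median and mean differed in sign for storage proteins (-0.302 and 0.0238) and chlorophyll breakdown (0.0584 and -0.0845).

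SESA4 and AT3G53040 gained 2.06 ± 0.39 and 3.07 ± 0.47, GA2OX2, which inactivates gibberellin, gained 2.24 ± 0.39, and L1L changed by -2.12 ± 0.45. ABI5 (1.44 ± 0.33, adjusted p = 0.081) and OLEO1 (-1.0 ± 0.28, adjusted p = 0.16) passed with all arrays but not with the compared arrays alone, and the other 8 genes named in advance were not called. OFP9 (-4.44 ± 0.78), AT4G26485 (-3.89 ± 0.59), AT5G01140 (-3.89 ± 0.47), AT4G36460 (-3.83 ± 0.62), AT1G61353 (-3.80 ± 0.70) and AT2G20625 (-3.66 ± 0.75) had the largest losses. The ratio changed for 3957 loci, 2101 upwards, and for 4106 on quantile values, 3733 after median centring (2385 upwards), 2622 without polysomal 20 DAP replicate 1, 1162 with the compared arrays alone (749 upwards) and 1158 with array weights (869 upwards). Over the 4 stages it changed for 3068 loci, and for 751 with array weights. From 15 to 20 DAP limma called 0 changes of the ratio (1086 at an unadjusted p under 0.05), also 0 on quantile values (529), and 22 without the 12 DAP arrays (3025 at an unadjusted p under 0.05), among them ATMG01030 with a gain of 2.80 ± 0.44. Without those arrays the organelle-encoded list gained by a median of 0.678 over that time (camera adjusted p = 2.6e-28; adjusted p = 0.091 with an estimated correlation).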

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

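The results here were singled out by the test of the difference between 12 and 20 DAP in the polysomal to total ratio, the interaction of fraction and stage. Of the tests of explanations, only the 1 on the age of the seed bulks and those on other splits of the arrays were chosen before the result was seen.

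The ratio changed for 3957 loci in the fit to all 24 arrays, and for 1162 with the compared arrays alone. Of 100 splits of the arrays 2 gave as many, the real one among them. The highest other gave 4395. It exchanged the fractions of all 6 arrays of 12 DAP and of total replicate 1 and polysomal replicate 3 at 20 DAP. The splits exchanged fractions within a stage, which breaks the difference between the fractions along with the change of the ratio. They therefore cannot tell whether chance explains the change of the ratio. Over the 4 stages 3068 loci changed, 2 of 100 splits gave as many and the highest other gave 6653. The same limit holds for these splits, and the large count points to a structure of the samples. By list, the median change of the log2 ratio was 3.04 for organelle-encoded transcripts, 0.625 for heat shock genes, -0.885 for fatty acid and triacylglycerol synthesis and -0.983 for oil body proteins. For the last list limma called 0 of 7 genes with the compared arrays alone, and the adjusted p = 0.17 with an estimated correlation. ATMG01240 (6.69), AT5G27889 (6.40), ATMG00450 (6.23), ATMG01030 (6.08), AT2G07798 (6.04) and AT4G18690 (5.79) gained most. OFP9 (-4.44), AT4G26485 (-3.89), AT5G01140 (-3.89), AT4G36460 (-3.83), AT1G61353 (-3.80) and AT2G20625 (-3.66) lost most.

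Mitochondrial transcripts were less depleted from polysomes at 20 than at 12 DAP. The narrow range of the 12 DAP arrays is argued against as the whole cause, because the median ratio also gained 0.738 from 15 to 20 DAP, a difference those arrays do not enter, with 85 of 92 loci up, 5 past the threshold (camera adjusted p = 1.5e-31; adjusted p = 0.048 with an estimated correlation, but 0.091 for the whole organelle-encoded list, whose median was 0.678). From 12 to 15 DAP the gain was 1.55 on quantile values, which give every array one range, against 2.49 as deposited. On quantile values the lower quartile was 0.733, and 47 of 92 loci passed the threshold upward. One range for all arrays thus shrank the gain but did not remove it. It cannot undo a compression of single genes, so how much of this step the 12 DAP arrays made stays open. From 15 to 20 DAP the ratio rose because the mitochondrial level fell in total RNA. Above the array median it was 5.46 to 5.56 there at 15 DAP and 4.59 to 4.97 at 20 DAP. In polysomal RNA it was 3.92 to 4.17 and 4.03 to 4.13. A fall of these transcripts to the low end in total RNA is argued against by their median level at 20 DAP, at percentile 95.8 of the array. Non-polysomal RNA carried into the later polysomal samples stays open, since the spread of nuclear ratios beyond replicate error fell to 0.77 of its value from 15 to 20 DAP (0.682 to 0.525), as does an untested difference between the stages themselves. From 12 to 15 DAP, where more of the gain fell, that spread moved from 0.79 to 0.682.

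The 12 DAP arrays had a narrow range and poor agreement between replicates. Seed bulks of slightly different age are argued against as the main source of the deviations of an array. These followed the change from 12 to 15 DAP with a squared correlation of at most 0.00598. The correlation ran over all loci, each with its own noise, so it could not show a small part played by age. A separate summary of the probes of the 12 DAP arrays is argued against by 132 values shared to all 9 decimals between a 12 DAP and a later array, in 53 of 108 pairs, against 0 for random decimals of that length, where ties are rare. That is 1.22 per pair, against 0.8 per pair of 12 DAP arrays and 3.86 per pair of later arrays. Shared values of summarized probe sets do not settle whether the arrays were also normalized together. Weak or uneven hybridisation stays open, as do untested real differences between the seed bulks, since even genes bright at both stages had a median SD 3.5 times that of 15 DAP in total RNA (0.376 against 0.108) and 5.07 times in polysomal RNA (0.524 against 0.103).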

How the results depend on the processing

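Fits without the 12 DAP arrays, comparisons with 15 in place of 12 DAP, and the compared arrays alone for lists and named genes were chosen only after the data had been seen. The array number, 3 per group, limits precision, and genes near background on an array cannot show a fall, so small changes of dim genes are the least certain. A test on all non-control probe sets was not run, because the table holds 1 probe set per locus. Where a value below differs from that of the report the cause was not tested, except where fewer genes or arrays entered the fit. Gene counts stayed within 1.5 times with trend and robust settings in 17 of 17 results, with a 2-fold threshold in 13 of 14, with median centring in 16 of 17 and with the dimmest loci left out in 15 of 17. With the replicate number as a block 17 of 17 gene counts stayed within that bound (total RNA over the 4 stages 17009 against 17005), as did all 56 lists, while 3 named genes fell short under the block (268 kept their call) and 10 under a block within each stage (139 kept it). Total and polysomal arrays of 1 stage and number deviated with r from -0.0212 to 0.0213, and 5 of 12 matched best with their own number, a hint from the data and not the design. Over 84 pairs of any 2 groups with 1 number r ran from -0.0594 to 0.244, with 7 over 0.1.

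Quantile values gave, for total RNA, 10640 loci over the 4 stages, 10181 from 12 to 15 and 245 from 15 to 18 DAP. For polysomal RNA they gave 11171, 11743 and 190, and 12041 from 12 to 20 DAP. The fractions differed for 762, 344 and 189 loci at 15, 18 and 20 DAP, and the relation of the fractions was 0.69. Lists past the threshold numbered 8, 2 and 2 for the fractions at 12, 15 and 18 DAP and 8 for the change of the ratio. Ribosomal proteins reversed on polysomes (-0.357), as did CRA1 (0.09), DOG1 (-0.88) and ABI3 (0.00). CRA1 reversed in total RNA (0.22), EM1 for the fractions at 12 DAP (0.39), FUS3 (-0.09), LEC1 (0.20) and CRA1 (0.18) at 20 DAP, and FUS3 (-0.48) and EM1 (-0.55) for the change of the ratio. Of 56 lists 35 kept their direction and side of the threshold and 20 fell short, and of the named genes 231 kept both, 27 fell short, 3 passed anew and 10 reversed.

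Cyclic loess gave 10340, 10558 and 8467 loci for total RNA over the 4 stages, from 12 to 20 and from 12 to 15 DAP, and 9520, 9568 and 8997 for polysomal RNA. The fractions differed for 2051 and 1379 loci at 15 and 18 DAP, the ratio changed for 2533 and over the 4 stages for 1823, and the relation was 0.702. Lists past the threshold numbered 7, 1, 1 and 1 for the fractions from 12 to 20 DAP. In total RNA it reversed oil body proteins (-0.996), ribosomal proteins (-0.795), translation factors (-0.429) and hormone and dormancy genes (-0.208), with AT2G18540 (-0.20), PAP85 (-0.37), OLEO5 (-0.97), ABI3 (-0.11), DOG1 (-0.75), OLEO1 (-1.76), EM1 (-1.09) and EM6 (-0.98). On polysomes it reversed ribosomal proteins (-1.04), translation factors (-0.739), organelle-encoded transcripts (-1.21) and non-coding RNA genes (0.017), with ABI3 (-0.80), DOG1 (-1.52), EM1 (-0.85) and EM6 (-1.41). FUS3 (-0.22), LEC1 (0.14), CRA1 (0.23) and OLEO1 (0.02) reversed for the fractions at 20 DAP, and FUS3 (-0.36) and CRA1 (0.10) for the change of the ratio. Of 56 lists 28 kept both and 20 fell short, and of the named genes 232 kept both and 20 fell short.

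With 15 in place of 12 DAP total RNA gave 1022 loci over the stages left and 1407 to 20 DAP, polysomal RNA 826 and 938, and limma called 0 changes of the ratio by either test (1086 to 20 DAP and 691 over the stages at an unadjusted p under 0.05). The same without the 12 DAP arrays gave 4658, 5335, 3139 and 3503, then 22 changes of the ratio to 20 DAP and 1 over the stages, with a relation of 0.606. Without the 12 DAP arrays the counts were 3720 and 2 for total RNA from 15 to 18 and 18 to 20 DAP, 3242 for polysomal RNA from 15 to 18 DAP, and 8643, 6887 and 4139 for the fractions at 15, 18 and 20 DAP, with 5 lists at 20 DAP, each of which lost its call with an estimated correlation (adjusted p = 0.098 to 0.47). Array weights gave 2367 and 6218 loci from 15 to 18 DAP in total and polysomal RNA, 4 from 18 to 20 DAP in polysomal RNA, 1590, 8534, 7248 and 7127 for the fractions from 12 to 20 DAP, and 1158 and 751 for the ratio to 20 DAP and over the 4 stages. The compared arrays alone gave 401 and 4265 from 15 to 18 DAP, 1573, 6196, 4328 and 3416 for the fractions, and 1162 for the ratio, and 224 named genes kept both direction and side of the threshold while 47 fell short.

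Leaving out the dimmest loci gave 14430 and 14114 loci for polysomal RNA from 12 to 20 and 12 to 15 DAP, where fewer genes were tested, a relation of 0.849 and 8, 4 and 8 lists for the fractions at 12 and 20 DAP and the ratio. Median centring gave 5344 loci at 15 DAP and 3 lists at 18 DAP, with reversed values for CRA1 in total (0.25) and polysomal RNA (0.06) and LEC1 at 20 DAP (0.07). The 2-fold threshold gave 2125 loci for the mean of the stages. With limma's fry the lists numbered 13, 12 and 6 for the fractions at 12, 15 and 20 DAP and 10 for the ratio, and with an estimated correlation 1, 1 and 1 at 15, 18 and 20 DAP.

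Leaving out each array in turn, with fewer arrays in the fit, gave 313 to 1033 loci from 15 to 18 DAP in total RNA and 332 to 972 in polysomal RNA. The fractions gave 1756 to 4005, 604 to 2828 and 399 to 1323 at 15, 18 and 20 DAP, the change of the ratio 2622 to 4916, and the relation 0.82 to 0.838. Lists ranged from 2 to 6 at 18 DAP and from 1 to 4 at 20 DAP. Genes not called whose sign moved were ABI3 (-0.22 to 0.67), FUS3 (-0.28 to 0.35) and LEC1 (-0.04 to 0.59) for the fractions at 12 DAP, FUS3 (-0.03 to 0.18) and LEC1 (-0.21 to 0.04) at 20 DAP, and FUS3 (-0.27 to 0.37) and EM1 (-0.14 to 0.15) for the change of the ratio. Of 408 gene counts so obtained 382 stayed within 1.5 times and 26 fell below, and of the list results 1332 kept both and 12 fell short. Of the named gene results 6299 kept both, 188 fell short, 2 passed anew and 15 reversed.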

Other observations

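The families below, the test on the insertion of chromosome 2 and the fits without the 12 DAP arrays were chosen only after the data had been seen, and the counts of splits before.

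The FLA, ENODL, KCS and AGP gene families fell in total RNA between 12 and 20 DAP. Families were formed from gene symbols that share a prefix, 182 with at least 10 members, and those given here were called in 1 direction as deposited, on quantile values and under cyclic loess. FLA5 and ENODL4, surface glycoproteins, changed by -5.94 ± 0.36 and -6.07 ± 0.40 in total RNA, and KCS6, which lengthens fatty acids for wax, by -4.49 ± 0.50. Of 19 FLA genes 18 fell and 0 rose (median -2.16, camera adjusted p = 1.3e-05; 0.0076 with an estimated correlation), and of 22 ENODL genes 19 fell (-1.49, adjusted p = 6.4e-05; 0.0076). Of 21 KCS genes 15 fell and 1 rose (-2.53, adjusted p = 2.3e-04; 0.0066), and of 30 AGP genes 24 fell and 2 rose (-1.93, adjusted p = 4.2e-05; adjusted p = 0.078 with an estimated correlation). In the same comparison 17 of 18 flavonoid, 10 of 12 mucilage and all 5 silique markers fell and 0 rose. VPS28-2 and VPS60.2, of vesicle sorting to the vacuole, rose by 3.86 ± 0.45 and 3.11 ± 0.21, and of 29 VPS genes 24 rose and 2 fell (2.15, adjusted p = 2.1e-07; 0.0044).

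Other families moved between the fractions. UGT87A2 and UGT71C5, which attach sugars to small molecules, gained 3.08 ± 0.52 and 2.79 ± 0.36 in the polysomal to total ratio from 12 to 20 DAP, and of 58 UGT genes 14 gained and 0 lost (median 0.802, adjusted p = 3.8e-05; 0.0051 with an estimated correlation). PUB25, of protein tagging with ubiquitin, gained 3.11 ± 0.42, and of 22 PUB genes 9 gained and 1 lost (0.842, adjusted p = 0.0096; 0.040). The UGT and PUB gains rest on the 12 DAP arrays, which stand apart. They were not tested with the compared arrays alone or from 15 to 20 DAP. Over the mean of 15 to 20 DAP, without the 12 DAP arrays, FLA2 was lower on polysomes by -2.48 ± 0.28 and SEC3B, of vesicle docking, higher by 1.03 ± 0.21. Of 19 FLA genes 12 were lower (-0.694, adjusted p = 6.3e-05) and of 15 SEC genes 15 were higher (0.583, adjusted p = 8.9e-04), with adjusted p = 0.24 and 0.28 with an estimated correlation. EXT10 was lower by -5.01 ± 0.35 over that time and NHL22 higher by 1.49 ± 0.16.

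Nuclear loci in the mitochondrial insertion of chromosome 2 were lower on polysomes at 12 DAP, and a candidate explanation is sequence shared with the mitochondrial genome. Of 99 loci there 96 were lower, 92 past the threshold, with a median of -4.13, against -1.09 for 9 neighbouring loci and -4.45 for mitochondrial loci. Of the 99, 32 had values identical to those of a mitochondrial locus, and the other 67 had a median of -3.93. At 20 DAP the median was -0.633. For the 32 with identical values the arrays do not tell the locus from the mitochondrial one, wherever the bounds are set. For the other 67 the values go with shared sequence. That stays a hypothesis because the bounds of the insertion were set on the same data, and no biological explanation was tested.

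Of 100 splits only the real one reached the count for changes over the 4 stages in total RNA (17005 loci, highest other split 14987). The same held for polysomal RNA (21808, highest other 20604) and for the mean difference of the fractions (10812, highest other 429). Chance is argued against for the last. The counts of 14987 and 20604 point to a structure of the samples. The 12 DAP arrays stand apart, so splits over the stages cannot tell a change of the seeds from a difference of those arrays. For the single steps the 10 splits are too few for a share under 0.05. In total RNA the real and highest other counts were 17441 and 4 from 12 to 20, 15273 and 0 from 12 to 15, 722 and 1 from 15 to 18, and 0 and 13 from 18 to 20 DAP. In polysomal RNA they were 21739 and 0, 21192 and 0, 742 and 0, and 0 and 0, and for the fractions 8750 and 1535, 3295 and 0, 2251 and 0, and 999 and 0 from 12 to 20 DAP. For the fractions the median count of the other splits was 848 at 12 DAP and 0 at each later stage.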
